A study of Mus musculus with 6 samples.

How the data were processed

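RNA sequencing of 6 libraries was analysed, 3 of CD93pos and 3 of CD93neg HSCs, grouped by the titles in the labels. Per the labels' protocols, the marrow was depleted of lineage-positive cells with magnetic beads before the sort, libraries came from a low-input kit, and reads were paired at 50 bp with a stated depth of 15 M reads. The labels state 3 biological replicates, and do not say which animals gave which library.

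The submitters' processing notes name STAR, featureCounts from Subread 1.5.0-p1 and DESeq2 1.26, with the builds GRCm38 and mm10. Annotation release and strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. The authors deposited a signal table of gene counts divided by a size factor per library, for 47937 genes. A second table deposited by the authors gives the mean signal, the log2 fold change and its standard error, the Wald score, and the p-value and adjusted p-value of each gene. Because 1 read is worth a fixed step in each library, whole reads were recovered for 100% of the values above 0, within a tolerance of 0.001. Size factors and totals differ between libraries, and many genes have no read in a CD93neg library, so fold changes on a log scale depend on the pseudocount.

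Genes with a mean normalized count of at least 10 were tested, 11805 in all. The test was limma 3.58.1 (lmFit, eBayes with a trend) on log2(normalized count + 1), two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale. It can understate the change of low genes, and can give large values where 1 or more libraries of a group are at 0, even where the group means are close. Count tests, edgeR 4.0.16 and DESeq2 1.42.0, were run on the recovered reads as alternatives in R 4.3.3. limma's camera with a preset correlation of 0.01 tested 47 of the 48 gene lists, those with at least 4 tested members, and 11 were called. With an estimated correlation 0 were called. The estimate lay below the preset for G2 and mitosis genes (0.0078) and dendritic cell markers (0.0063). A high correlation is therefore not what ended every call. fry, which does not compare a list with other genes, called 4. The lists, the tests and most alternatives were fixed before the data were examined. Gene symbols were those the authors gave with their fold changes. Positions and biotypes came from GENCODE M21 on GRCm38, in which 47224 of the 47937 IDs were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.

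Named genes were the 7 genes of the sort gate and, in each direction, the 7 with the largest fold change and the 7 with the smallest p among genes past the threshold whose groups did not overlap. With fewer than 7 passing, those with the smallest unadjusted p were taken up to 7, as values. Predicted genes (Gm with digits, names ending in Rik), pseudogenes, mitochondrial genes, immunoglobulin and T cell receptor segments and genes without a symbol were left out of these rankings. Up to 4 members with the smallest p were added for each list that camera called or that had a member past the threshold.

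Reads of each list as CPM (counts scaled to 1e6 assigned reads) were added after the data were seen, and compared with an exact two-sided permutation test, whose adjusted p over the 48 lists was at least 0.3. A fold against a group with no read is a lower bound from the CPM of the summed group, with a floor of 3 reads over the group. Such bounds depend on the depth of the unread group: each was 1.79 times lower without CD93neg replicate 2 where CD93neg was unread, and 1.73 times lower without CD93pos replicate 1 where CD93pos was. Floors cover counting error only, and reads from amplified libraries are not independent molecules. P-values of single genes measure the spread between these libraries. Those of camera at the preset correlation set list members against other genes, taken as nearly independent, and do not measure that spread alone. Estimated correlations were 0.84, 0.72 and 0.59 for the neutrophil, ribosomal protein and B lineage lists.

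The scripts were tested on simulated counts for the 11805 genes. With a coefficient of variation of 0.3, limma recovered 100% of 100 genes changed by a log2 fold of 3 and 100% of 100 changed by 6, with 7 false calls. At the common coefficient edgeR estimated in these libraries, 1.64, limma and edgeR recovered 0% at either size. Each simulation gave every gene and library the same coefficient, unlike the real libraries. Alternatives covered the pseudocount, filter, scaling, test, replicate block and each library left out. Added after seeing the data were library quality weights, thinning to 2832653 reads and DESeq2 with each library left out.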

Results

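Polyadenylated RNA was sequenced from haematopoietic stem cells (HSCs) sorted from the bone marrow of 8-week-old wild-type C57BL/6 mice. HSCs are the self-renewing cells from which the blood lineages arise. They were gated as lineage-depleted, Kit and Sca-1 positive, CD34, CD48 and Flt3 negative and Slam1 positive cells, and divided by the surface receptor CD93 into CD93-positive (CD93pos) and CD93-negative (CD93neg) fractions, with 3 libraries each. The reads assigned to genes numbered 9509304, 5794528 and 7152750 in CD93pos replicates 1, 2 and 3, and 2832653, 4614396 and 3003095 in CD93neg replicates 1, 2 and 3. Reads were found for 17334, 12564 and 15254 genes in the CD93pos libraries and for 4429, 10752 and 12029 in the CD93neg libraries. Of the 11805 tested genes, CD93neg replicate 1 had no read for 71.0%, against 26.4% and 16% in the other CD93neg libraries and 2.10% to 13.5% in the CD93pos libraries. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.70 to 0.88 within CD93pos, 0.23 to 0.46 within CD93neg and 0.28 to 0.57 between the groups.

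The comparison asks how CD93pos and CD93neg HSCs differ in their transcripts. Genes of G2 and mitosis and of DNA replication lay higher in CD93pos HSCs as groups, as did mast cell and basophil genes and the Y-linked genes, by camera with a preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.104, 0.747, 0.474 and 0.207 in that order). fry does not compare a list with other genes. It called the G2 and mitosis, mast cell and basophil, and Y-linked lists (adjusted p = 0.00203, 0.0127 and 0.00264). It did not call the DNA replication list (adjusted p = 0.051). Neutrophil, B lineage and dendritic cell genes lay lower in CD93pos, with nearly all reads of the first 2 groups in CD93neg replicates 2 and 3. Their calls were also lost with an estimated correlation (adjusted p = 0.747, 0.747 and 0.192), and fry called none of the 3 (adjusted p = 0.484, 0.521 and 0.272). Reads of the 34 G2 and mitosis genes made up 5635 ± 545 CPM (counts scaled to 1e6 assigned reads) in CD93pos and 1765 ± 1392 in CD93neg (SD, n = 3 each), a ratio of 3.19 with no overlap between the groups. CD93neg replicate 1 had 3369 CPM, and without it the ratio was 5.85. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow, and an adjusted p of 0.3 over the lists. Lists that camera did not call also had no overlap, such as hypoxia response genes (higher in CD93pos) and cholesterol synthesis genes (lower). No single gene passed the test: limma called 0 of 11805 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0558.

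Cd93, which encodes the receptor the cells were sorted on (ENSMUSG00000027435.8, GRCm38 chromosome 2, 148436640 to 148443563), had 906, 1001 and 550 reads in the CD93pos libraries and 0, 419 and 38 in the CD93neg libraries. Its mean normalized count was 515 ± 244 in CD93pos and 153 ± 215 in CD93neg (SD, n = 3 each). The groups overlapped: CD93neg replicate 2 had a normalized count of 399, above the 338 of CD93pos replicate 3, so the transcript did not separate that library from CD93pos and groups are given as labelled. The log2 fold change was 4.06 with an SE of 2.54 and a limma adjusted p of 0.541, so the difference did not exceed the spread between replicates. Without CD93neg replicate 1 the log2 fold change of Cd93 was 1.63. Among the other gate genes, Kit, the stem cell factor receptor, had a log2 fold change of -0.93. Slamf1 had 2.49, with 544, 210 and 969 reads in CD93pos and 0, 352 and 269 in CD93neg. Ly6a, which encodes Sca-1, had 242, 256 and 231 reads in CD93pos and 0, 481 and 455 in CD93neg. Transcripts of the genes selected against were also read. Cd34 had 3216, 1603 and 2496 reads in CD93pos and 1715, 0 and 767 in CD93neg, and Cd48 had 640, 371 and 487 against 0, 146 and 67. Flt3 had 236, 0 and 195 reads against 0, 172 and 13. None of the 7 gate genes passed the threshold, and the directions of Cd34, Flt3, Ly6a and Slamf1 turned under other settings.

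G2 and mitosis genes were higher in CD93pos as a group. All 34 were tested, and all 34 had a positive fold change, as did 79.9% of all tested genes. Camera called the list higher (median log2 fold change 5.69, which is 3.33 above that of all genes, adjusted p = 2.7e-10). With an estimated correlation the adjusted p = 0.104, so that call was lost. The estimate was 0.0078, below the preset 0.01, so a higher correlation was not the reason. fry called the list (adjusted p = 0.00203). None of the 34 passed over all genes tested, and 11 were higher when adjusted over the list alone. Every member was read in each CD93pos library, while 11, 14 and 20 were read in CD93neg replicates 1, 2 and 3. Ccna2, the cyclin of S phase and G2, had 1604, 1274 and 1314 reads in CD93pos and 0 in each CD93neg library, at least 650-fold higher against a floor of 3 reads over the CD93neg group. Nuf2 and Ndc80, components of the kinetochore complex that holds microtubules, were at least 473-fold and 366-fold higher by the same measure. Kif20a, a kinesin of cytokinesis, was at least 362-fold higher. These 4 genes had limma adjusted p-values of 0.0558. They were among 543 tested genes read in all 3 CD93pos libraries and in no CD93neg library, against 0 genes the other way. The sparse CD93neg replicate 1, with no read for 71.0% of tested genes, limits the latter count. In CD93neg replicates 2 and 3, 27 tested genes were read that had no read in any CD93pos library. Ccna2 lies on chromosome 3 (GRCm38, 36564865 to 36572150). Y-linked, neutrophil and B lineage transcripts differed between the same libraries, as given with those lists. Mast cell and basophil markers and erythroid genes had positive medians as well (6.41 and 3.89), the erythroid list without a camera call.

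The other genes with the smallest unadjusted p among those higher in CD93pos were Ckap2l, Ncaph and Neil3, none with a read in CD93neg. Ckap2l, a mitotic spindle protein, had a mean normalized count of 1281 ± 467 in CD93pos (SD, n = 3), at least 1018-fold above the floor. Ncaph, a condensin subunit, and Neil3, a DNA glycosylase, were at least 490-fold and 396-fold above it. All 3 had an adjusted p of 0.0558 and are given as values, not as changes.

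S phase and DNA replication genes were also called higher by camera, with 35 tested, a median log2 fold change of 4.02 and an adjusted p = 0.000648. The adjusted p = 0.747 with an estimated correlation, fry did not call the list (adjusted p = 0.051), and 3 members were higher when adjusted over the list alone. Their reads amounted to 9612 ± 1404 CPM in CD93pos and 4124 ± 1865 in CD93neg (SD, n = 3 each), without overlap (exact permutation p = 0.1). Pola1, the catalytic subunit of DNA polymerase alpha, Chaf1a, a histone chaperone subunit, and Ccne1, cyclin E1, had no read in any CD93neg library. They were at least 408-fold, 277-fold and 91.7-fold higher in CD93pos. Pola1 had 1722, 509 and 397 reads there, and its bound was 244-fold without CD93pos replicate 1. Mcm10, a replication initiation factor, had a log2 fold change of 6.56 (SE 1.97, limma adjusted p = 0.162). Without CD93neg replicate 3 the camera adjusted p of this list was 0.0912.

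**Figure D1:**
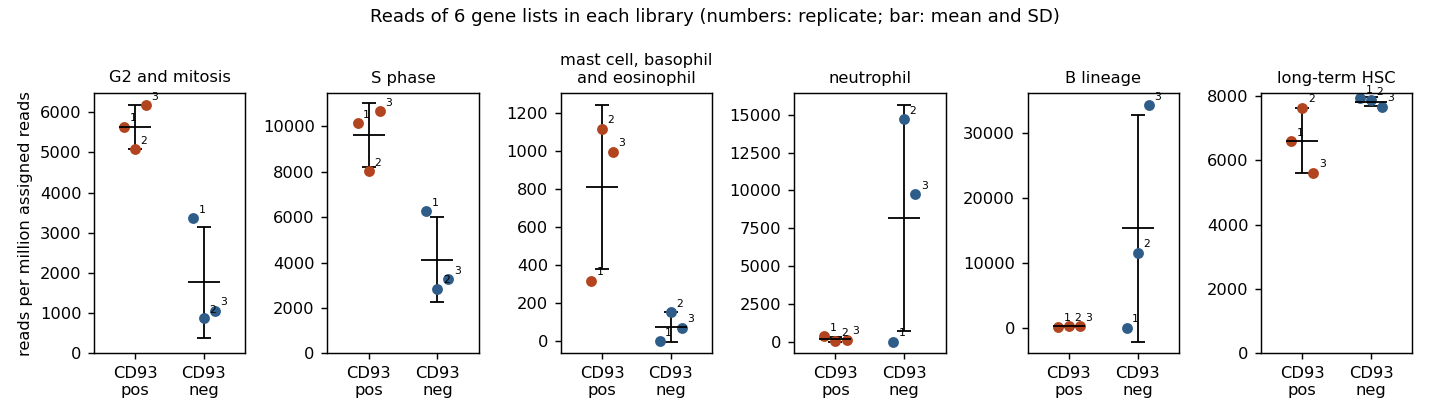
Reads of 6 fixed gene lists in CPM (vertical axis, linear) in each of the 3 CD93pos and 3 CD93neg libraries. Points are libraries with their replicate number, and horizontal bars with whiskers are the mean and SD. G2 and mitosis reads average 5635 CPM in CD93pos and 1765 in CD93neg, while neutrophil and B lineage reads are high in CD93neg replicates 2 and 3 and near 0 in replicate 1.

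Markers of mast cells, basophils and eosinophils were called higher in CD93pos (9 tested, median log2 fold change 6.41, camera adjusted p = 0.000596). The adjusted p = 0.474 with an estimated correlation, and 6 members were higher when adjusted over the list alone. Prss34, a basophil and mast cell protease, had 109, 3160 and 3058 reads in CD93pos and none in CD93neg, at least 981-fold higher, or 1673-fold without CD93pos replicate 1 (GRCm38 chromosome 17, 25298394 to 25300165). Ms4a2 and Fcer1a, subunits of the high-affinity IgE receptor, were at least 139-fold and 44.4-fold higher, with 90, 668 and 139 and 74, 176 and 36 reads in CD93pos. Without CD93pos replicate 2 these bounds were 47.9-fold and 23-fold, and without CD93pos replicate 1 that of Ms4a2 was 217-fold. Hdc, which makes histamine, was at least 133-fold higher. Without CD93neg replicate 3 the camera adjusted p was 0.0815.

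The 4 Y-linked genes were called higher in CD93pos (median log2 fold change 6.85, or 6.96 with unread genes at their bound, camera adjusted p = 0.000112). The adjusted p = 0.207 with an estimated correlation, and all 4 passed when adjusted over the list alone. Ddx3y had 855, 328 and 243 reads in CD93pos and 0 in each CD93neg library, at least 221-fold higher. Kdm5d and Uty were at least 70.4-fold and 53-fold higher, and without CD93pos replicate 1 the bound of Kdm5d was 41.4-fold. Eif2s3y had 888, 750 and 768 reads in CD93pos and 1, 0 and 0 in CD93neg. The labels describe the mice as male. Xist, the RNA of the inactive X chromosome, had 0, 0 and 12 reads in CD93pos and 0, 2419 and 1143 in CD93neg. It was outside the rule for named genes and was chosen after its values were seen.

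Neutrophil markers were called lower in CD93pos (16 tested, median log2 fold change -4.84, or -5.06 with unread genes at their bound, camera adjusted p = 9.5e-12; adjusted p = 0.747 with an estimated correlation). None passed when adjusted over the list alone. Reads of the list amounted to 0, 14723 and 9749 CPM in CD93neg replicates 1, 2 and 3, and to 341, 18.1 and 128 in the CD93pos libraries. Retnlg had 1026 and 770 reads in CD93neg replicates 2 and 3, and Mmp9, a secreted protease, had 701 and 568. Fcnb had 862 and 237. Ly6g, the antigen by which neutrophils are recognised, had 200 and 55 and none in CD93pos, at least 183-fold lower there, or 70.5-fold without CD93neg replicate 2. All 4 were at 0 in CD93neg replicate 1. MHC class II presentation genes, not called by camera (10 tested, adjusted p = 0.144; 0.895 with an estimated correlation), had 4504 and 4735 CPM in CD93neg replicates 2 and 3, 0.353 in CD93neg replicate 1 and 438 to 520 in CD93pos. Mitochondrial reads made up 1.61% and 2.15% in CD93neg replicates 2 and 3, 0.519% in CD93neg replicate 1 and 0.718% to 1.04% in CD93pos.

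B lineage markers were called lower in CD93pos (11 tested, median log2 fold change -2.88, or -3.78 with unread genes at their bound, camera adjusted p = 4.2e-06). The adjusted p = 0.747 with an estimated correlation, and no member passed when adjusted over the list alone. Igkc, the kappa light chain constant gene, had 28862 and 42962 reads in CD93neg replicates 2 and 3, none in CD93neg replicate 1 and 0, 0 and 176 in CD93pos. Ms4a1 and Cd79a, B cell surface genes, were at least 534-fold and 465-fold lower in CD93pos, where neither was read. Pax5, the B lineage transcription factor, was at least 59.5-fold lower, with 0, 18 and 65 reads in CD93neg, and at least 18.1-fold lower without CD93neg replicate 3. Dendritic cell markers were called lower as well (7 tested, median log2 fold change -1.99, camera adjusted p = 1.3e-05; adjusted p = 0.192 with an estimated correlation). Their members with the smallest p were Ly6d, Irf8, Tcf4 and Siglech. Irf8, a transcription factor of dendritic and monocytic cells, had 99, 35 and 216 reads in CD93pos and 590, 624 and 252 in CD93neg. Tcf4 had 6941 reads in CD93neg replicate 1 alone, against 904 and 1103 in the others. Ly6d was at least 242-fold lower in CD93pos, or 137-fold without CD93neg replicate 3. Siglech, read only in CD93neg replicate 3, was at least 80.9-fold lower, or 145-fold without CD93neg replicate 2.

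**Figure D2:**
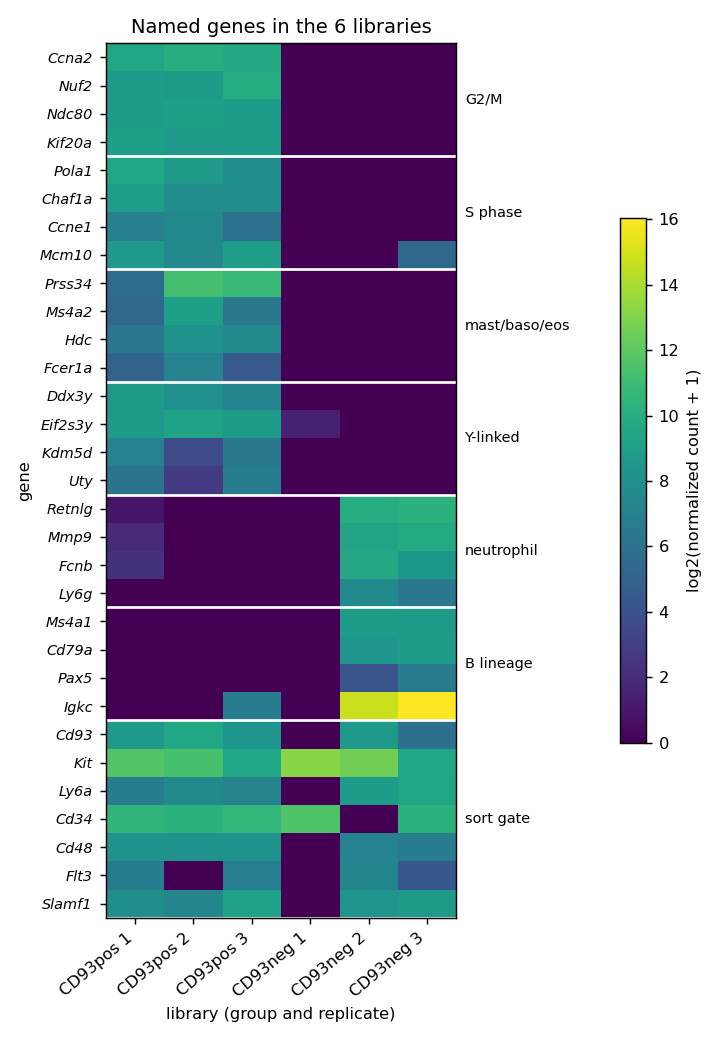
Colour gives log2(normalized count + 1) for 31 named genes (vertical axis, grouped by fixed list) in the 6 libraries (horizontal axis, group and replicate). Ccna2, Nuf2, Ndc80 and Kif20a are at 0 in all 3 CD93neg libraries, and Retnlg, Mmp9, Fcnb and Ly6g are at 0 in CD93neg replicate 1.

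Over all tested genes the median log2 fold change was 2.36 toward CD93pos, and 0.44 without CD93neg replicate 1, so lists were read against that shift. Cytosolic ribosomal protein genes were called lower relative to other genes (76 tested, camera adjusted p = 8.5e-08; adjusted p = 0.895 with an estimated correlation) with a median of -0.09. Rpl8, Rpl13 and Rps19 had log2 fold changes of -0.46, -0.42 and -0.43. Rpl27 had 883, 548 and 659 reads in CD93pos and 0, 591 and 192 in CD93neg, with mean normalized counts of 414 and 287, and a log2 fold change of 2.91 that includes the 0 of CD93neg replicate 1. Actin cytoskeleton and migration genes (38 tested, median 0.53, camera adjusted p = 0.00978) were called lower although their median was above 0. Myeloid lineage genes (20 tested, median 0.13, adjusted p = 0.00978) and MHC class I genes (15 tested, median 0.77, adjusted p = 0.0281) were also called lower with medians above 0. The adjusted p = 0.895 with an estimated correlation for each of these 3 lists, and only 1 member, Coro1a, passed when adjusted over the list alone. Coro1a, an actin-binding protein, had a mean normalized count of 2439 ± 162 in CD93pos and 5191 ± 623 in CD93neg. Rac2 and S100a4 had log2 fold changes of -0.77 and -4.17, and Myh9 of 3.05. In the myeloid list Prtn3, a granule protease, had -1.90. Mpo, myeloperoxidase, had 1622, 1092 and 3446 reads in CD93pos and 0, 3408 and 0 in CD93neg, with mean normalized counts of 1242 and 1081. Ms4a6c had 209, 189 and 194 reads against 0, 0 and 476, and its mean normalized count was 122 in CD93pos and 248 in CD93neg, opposite to its log2 fold change of 3.73. In the MHC class I list H2-D1 had -0.28, H2-T23 -4.54, Psmb9 -1.64 and H2-Q4 3.67. MHC class I and ribosomal protein genes have near-identical copies that can share reads, so their values are uncertain. Under quantile normalization the ribosomal, actin and MHC class I calls were lost. Without CD93pos replicate 1 the actin, myeloid and MHC class I calls were lost (adjusted p = 0.0623, 0.0623 and 0.0657). The myeloid and MHC class I calls were also lost without CD93neg replicate 2 (0.316 and 0.126) and without CD93neg replicate 3 (0.0815 and 0.0975).

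The genes with the smallest unadjusted p among those lower in CD93pos were Adgrg1, Aldh2, Coro1a, Rsrp1, Psap, Map3k1 and Tbc1d10c. They are given as values, since none passed the threshold. Adgrg1, an adhesion receptor, had mean normalized counts of 8206 ± 1119 in CD93pos and 12635 ± 1234 in CD93neg (SD, n = 3 each), with a log2 fold change of -0.63 (SE 0.12, limma adjusted p = 0.0558). Aldh2, mitochondrial aldehyde dehydrogenase, had 2224 ± 616 and 6086 ± 1267, with -1.47 (SE 0.29). Psap, a lysosomal protein precursor, Rsrp1 and Tbc1d10c had log2 fold changes of -1.08, -1.29 and -2.03. Map3k1, a kinase, had 17, 0 and 2 reads in CD93pos and 306, 79 and 52 in CD93neg.

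limma called 0 genes, with 1391 higher and 45 lower at an unadjusted p under 0.05. After quantile normalization these were 689 and 916. edgeR's quasi-likelihood test called 0, and DESeq2 on the recovered reads called 705, of which 659 were higher in CD93pos. The authors' deposited table holds the same 705 calls. Of these, 450 were at 0 in all 3 CD93neg libraries and 646 were at 0 in CD93neg replicate 1. The DESeq2 count ranged from 220 to 2446 when 1 library was left out, at 310, 245 and 220 without CD93pos replicates 1, 2 and 3 and 1339, 1094 and 2446 without CD93neg replicates 1, 2 and 3. The limma count was 707 without CD93pos replicate 2, 1873 without CD93neg replicate 3 and 1 without CD93neg replicate 1. That gene was Cd74, the MHC class II invariant chain, lower in CD93pos (log2 fold change -4.74, limma adjusted p = 0.00983), and it was chosen after its values were seen. Groups did not overlap for 2162 genes higher and 227 lower in CD93pos, 20.2% of tested genes against 10% by chance. The median half-width of the 95% interval of a log2 fold change was 5.20. In counts simulated with a single estimated spread for every gene and library, limma recovered 0% of genes changed by a log2 fold of 6. Real spread differed between genes and between libraries, so that share does not describe each gene.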

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

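Library quality weights, thinned reads, read shares and the DESeq2 counts with a library left out were chosen after seeing the data. Cd93 stayed above 0 and short of the threshold under every alternative run, from 1.63 without CD93neg replicate 1 to 5.95 without CD93neg replicate 2. The count of genes past the threshold, 0, became 206 with a pseudocount of 0.5 (204 higher, 2 lower) and 705 with DESeq2 (659 higher, 46 lower). With 1 library left out it ranged from 0 to 1873, from 0 to 1866 higher and from 0 to 7 lower. The causes were not tested. The 705 DESeq2 calls ranged from 220 to 2446 with a library left out. The total was lowest in CD93neg replicate 1, with a median of 13 reads per detected gene, and the quality weights gave that library the lowest weight. Depth alone did not account for its few genes. With every library thinned to the same total, 4429 genes were detected in CD93neg replicate 1 and 11962 in CD93neg replicate 3.

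The 11 list calls became 0 with an estimated correlation and 21 with quality weights, and ranged from 7 to 19 with a library left out. fry, which asks another question, called 4 lists: G2 and mitosis, Y-linked, mast cell and basophil, and erythroid genes. fry gave the other direction for ribosomal proteins and myeloid genes (adjusted p = 0.924 each), actin genes (0.644) and MHC class I genes (0.789), and quantile normalization did so for actin genes (0.438). Quantile normalization turned Flt3 to -0.90, H2-D1 to 0.30, H2-Q4 to -0.56, Ly6a to -1.42 and Rpl13 to 0.051. DESeq2 turned Cd34 to -0.012, Ly6a to -1.36 and, with no p-value given, Ms4a6c to -1.03, edgeR turned Ly6a to -1.29 and Ms4a6c to -0.97, and quality weights turned Ly6a to -1.81. With a library left out, Cd34 ranged from -0.44 to 5.36, Flt3 from -1.33 to 2.92, Ly6a from -1.95 to 2.79 and Slamf1 from -0.36 to 3.995. The difference in ribosomal protein reads ranged from -11494 to 2646 CPM. The causes were not tested. The Y-linked list had no value with a mean of at least 50. Among other values of named genes, 91 passed the threshold under an alternative and 1098 kept direction and side.

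With the replicate number as a block, limma called 24 genes (15 higher, 9 lower) and edgeR 7 (1 higher, 6 lower), with Ly6a at -0.060 in the latter. The limma block called the named genes Adgrg1 (adjusted p = 3.8e-09), Aldh2 (0.0033), Psap (0.00093), Rsrp1 (2.9e-20) and H2-D1 (0.00063), and the edgeR block called none of these 5 (adjusted p = 1 each) but called Igkc (1.5e-164). The block ended the camera call of the myeloid list (adjusted p = 0.0523). Deviations of libraries with the same number correlated at 0.04, 0.02 and 0.06, too low to pair them, although each library correlated best with its own number, a hint from the data and not the design.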

Other observations

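The tests of erythroid cells, of sex-linked genes and of cells in CD93neg replicates 2 and 3 were chosen only after the results were seen, as was the gene named in the next paragraph.

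Erythroid genes had a median log2 fold change of 3.89 over 17 tested, or 4.76 with unread genes at their bound. Camera did not call them (adjusted p = 0.0652; 0.895 with an estimated correlation), and fry did (adjusted p = 0.0198). Klf1, the erythroid transcription factor, had 1094, 375 and 1166 reads in CD93pos and none in CD93neg (limma adjusted p = 0.0558). Megakaryocyte and platelet genes had a median of 3.42 over 23 tested (camera adjusted p = 0.626), and their reads overlapped between the groups, at a ratio of 1.34 (exact permutation p = 0.3). Long-term HSC genes (35 tested, median 1.52, camera adjusted p = 0.130) and dormancy genes (24 tested, median 1.48, camera adjusted p = 0.310) were not called. Both medians were above 0 but below the 2.36 of all tested genes. Camera's direction for both lists was lower relative to other genes. Reads of the long-term HSC list numbered 6615 ± 1014 CPM in CD93pos and 7820 ± 143 in CD93neg (SD, n = 3 each; exact permutation p = 0.1). Ribosome biogenesis and Myc-responsive genes had 11257 ± 1167 and 6916 ± 202 CPM (exact permutation p = 0.1), and camera did not call them (adjusted p = 0.0747).

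G2 and mitosis genes were higher in CD93pos, and values argued against 3 technical explanations, low detection only for genes lost independently. Of 10000 lists matched on CD93pos mean, 0 had as few detections over the CD93neg libraries (45, against a matched median of 79), although in CD93neg replicate 1 alone 11.5% did. Matched genes were drawn independently, so a loss of the list's members together in a sparse library is not covered. Thinning left the list 3.16 above the median of all genes, from 3.33, and without CD93neg replicate 1 camera gave an adjusted p of 1.9e-15 at the preset correlation (0.104 over all libraries with an estimated correlation, so that call was lost). Erythroid progenitors in the CD93pos sort remain a candidate source, since the erythroid list lay 1.53 above the median of all genes. Its reads were only 1.15 times those in CD93neg, though without overlap (exact permutation p = 0.1). It had 20 detections over the CD93neg libraries against a matched median of 32, as few as in a share of 0.0003 of matched lists. The lineage depletion and gate were meant to yield HSCs, and whether such cells remained was not tested. A higher share of cycling cells among CD93pos HSCs may also account for the G2 and mitosis difference and was not tested apart from an erythroid source.

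Y-linked genes were read in CD93pos and Xist in CD93neg replicates 2 and 3. Low detection was argued against: a share of 0.0001 of 10000 matched lists, the smallest they can give above 0, had as few detections in those libraries. These lists too were drawn gene by gene, so a loss of the Y-linked genes together is not covered. Female donor cells in those libraries, and a wrong label or an exchange with an outside sample, stay open and were not tested. The Y-linked genes had 0 reads in each and Xist at least 1143, whereas the labels say male. These are the values that prompted those explanations. Each CD93pos library had at least 750 Eif2s3y reads. An exchange between the groups was not tested, and an exchanged library would keep its own sex-linked reads, so these values cannot decide it. For CD93neg replicate 1 sex cannot be told apart from low detection, with 1 Y-linked read and 0 of Xist. Where donors differed in sex, sex and CD93 cannot be separated in these libraries, and no comparison here corrects for it.

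Neutrophil and B lineage transcripts were read in CD93neg replicates 2 and 3. The test fixed beforehand argued against mature cells in all 3 CD93neg libraries, as 0.9977 of 10000 matched lists had as many detections. That test could hardly have come out otherwise for cells in 2 libraries, which allow at most 54 detections against a matched median of 57. In both replicates 2 and 3, 21 of 27 members lay above every CD93pos library (Ngp 21884 and 12681 reads, Ighm 20727 and 57889), which restates the pattern, so mature neutrophils and B cells there, which the lineage depletion would remove, stay open as a source. A single library was argued against, since the largest camera adjusted p with 1 CD93neg library left out was 0.0270 at the preset correlation (0.747 for each list over all libraries with an estimated correlation, so those calls were lost).

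The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes by limma, as did others (10 of 10 gave as many, highest other 1), and 11 lists by camera (4 of 10 gave as many, highest other 13). It gave 705 genes by DESeq2 (1 of 10 gave as many, highest other 320).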
